A study of Mus musculus with 16 samples.

How the data were processed

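RNA from the left ventricle of 16 C57BL/6J mice was measured on 16 arrays, 1 animal per array, in a design of sex by operation. Each of the groups male sham, male TAC, female sham and female TAC held 4 arrays. TAC stands for transverse aortic constriction, a band around the aortic arch that raises the pressure against which the left ventricle pumps. Per the labels' protocols, the mice were 12-14 weeks old, and 14 days passed between the operation and the isolation of total RNA, which was converted to biotin-labelled cRNA from an oligo(dT) primer and hybridised separately for each animal. The series text calls the arrays RAE 430A, while the probe set names and the platform annotation are those of the mouse 430A array.

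The deposited table holds the authors' signal intensity for each of 22690 probe sets, computed with GCOS, per the labels. The GCOS version, the algorithm settings and any filter are not given. The deposited intensities were on a linear scale and had already been scaled globally, as tested on the values: after 2% of the probe sets were trimmed from each end, the mean signal lay between 500.21 and 500.25 on all 16 arrays. That scaling was kept. Signals were transformed as log2(signal + 16), and every fold change below is a difference of means on this scale. The 64 AFFX control probe sets were left out, as were the 40% of the remaining probe sets with the lowest mean of log2(signal + 16) over the 16 arrays, a limit that corresponds to a signal of 130.8. This left 13576 probe sets for 8272 genes. Detection calls and background signals were not used here, so a dim probe set cannot be told from an unexpressed gene, and the number of arrays limits the precision.

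Probe sets were named from the platform annotation: 20380 had exactly 1 gene symbol, 691 had several and 1555 had none. The symbols were looked up by Entrez ID in a RefSeq table of the assembly GRCm38.p6, which held 20364 of the 1-symbol probe sets and changed 0 symbols. No gene was named from a probe set with several symbols.

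Differences were tested with limma 3.58.1 in R 4.3.3: 1 linear model with 4 group means over all 16 arrays, empirical Bayes moderation with an intensity trend, 2-sided tests and Benjamini-Hochberg adjustment over the 13576 probe sets, with adjusted p below 0.05 as the threshold. In each group, n = 4. The comparisons were TAC against sham in males, in females and averaged over the sexes, the female response minus the male response, and female against male within sham and within TAC. "Rose" and "fell" below refer to genes past that threshold. All adjusted p values of single genes come from this limma model or, where stated, from its alternatives. Those of Esr1, which the filter left out, come from the same model fitted to all 22626 probe sets without controls. The correlation between the responses of the sexes is across probe sets, which are not independent replicates.

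The comparisons, thresholds, 41 gene lists, alternatives and the rule for naming genes were fixed before the data were examined. For each TAC comparison and each comparison of the sexes, the rule takes the 10 largest rises and the 10 largest falls among probe sets with 1 symbol that passed the threshold and whose groups did not overlap, 1 probe set per gene, that with the highest mean over the 16 arrays. The highest mean was taken among all probe sets of a gene, before the threshold, so a gene that passed on another probe set alone was not taken. The genes that the rule takes with the highest mean among the passing probe sets instead were looked at after the values were seen. For the difference of responses it takes the 5 smallest p values in each direction. It also takes up to 4 members with the smallest p of each gene list, and a fixed set of cardiac and sex-linked genes. Other probe sets of a named gene were checked for direction. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, 1 probe set per gene, with Benjamini-Hochberg adjustment over the lists. Each call was repeated with an estimated correlation, and with fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Of the 41 lists, 39 had at least 4 measured genes. The skeletal muscle list, with 3 measured genes, and the erythroid list, with 2, were not tested. Members past the threshold were counted on the same 1 probe set per gene, with p adjusted over all 13576 probe sets and again adjusted over the list alone. A member that passed on another probe set alone is not in these counts.

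The alternatives fixed beforehand were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a filter on the dimmest 60%, no intensity trend, array weights, 1 probe set per gene, only the groups compared, a block for the replicate number, and each array left out in turn. After the data were seen, further alternatives were added: the 5' signal of the 18S rRNA control, the Gapdh 3' to 5' ratio or the difference between the clock genes Dbp and Arntl as a covariate, the removal of male TAC 4 together with female TAC 1, whose Arntl and Dbp signals stood apart from those of the other TAC arrays, and the alternatives first meant for single genes, applied to the gene lists. The model was tested on simulated data with 13576 probe sets, 200 of them changed, and normal noise drawn independently for each probe set and array. The real TAC comparisons called 17.8% of probe sets in males, 15.1% in females and 28.7% averaged, and real noise may be shared between probe sets. The simulated shares therefore do not give the sensitivity on the real arrays. In the simulation the model recovered 58.2% of log2 changes of 1 in the male TAC comparison and 56.7% in the female one, 94% in the average, 38.8% in the difference of responses, 55.2% between the shams and 50.7% between the TAC groups.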

Results

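The left ventricular transcriptome was profiled 14 days after TAC or a sham operation in male and female mice, with 4 arrays in each of the 4 groups. The series asks how the early response to pressure overload depends on sex. After the deposited scaling, the median signal of single arrays lay between 189.8 and 222.3, and the highest signal was 64395. Array profiles correlated at 0.927 to 0.958 within groups and at 0.89 to 0.928 between TAC and sham arrays. The first principal component held 28.2% of the variance and separated all 8 TAC arrays from all 8 sham arrays.

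Measures of RNA and labelling quality also moved with the operation. The 5' probe set of 18S rRNA had a log2 signal of 13.35 ± 0.50 (SD, n = 4) in male shams, 10.34 ± 1.89 in male TAC, 11.96 ± 0.91 in female shams and 10.20 ± 0.60 in female TAC. TAC minus sham was -3.01 in males (exact permutation p = 0.0571, adjusted 0.0685 over 6 tests) and -1.75 in females (exact permutation p = 0.0286, adjusted 0.0429), where 0.0286 is the smallest p that 4 against 4 arrays allow. Male TAC 5 stood apart from its group, at 13.2 against 9.11 to 9.57 on the other arrays. Results below with the 18S signal as a covariate therefore lean on this array. The ratio of the 3' to the 5' Gapdh signal was 0.885 ± 0.039 in male shams and 1.08 ± 0.07 in male TAC, and 0.865 ± 0.058 in female shams and 0.990 ± 0.030 in female TAC (exact permutation p = 0.0286 in each sex, adjusted 0.0429). The ratio of the 3' to the 5' actin signal was 1.44 ± 0.11 in male shams and 1.71 ± 0.26 in male TAC, a difference that did not pass (0.267, exact permutation p = 0.114, adjusted 0.114), and 1.36 ± 0.03 in female shams and 1.72 ± 0.20 in female TAC (0.358, exact permutation p = 0.0286, adjusted 0.0429). The labels give no batch, and scan dates were not analysed here. Every TAC difference below therefore stands beside a quality difference between the same arrays. The sample titles end in a running number that follows the groups in consecutive blocks: male TAC, female TAC, male sham, female sham. What it counts is not stated. If it is an order of processing, that order cannot be told apart from operation and sex.

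The sex labels were checked with genes of the sex chromosomes. Xist, the RNA that coats the inactive X chromosome, had a mean signal of 3526 ± 517 (SD, n = 4) in female shams and 4904 ± 510 in female TAC, against 285 ± 47 in male shams and 281 ± 81 in male TAC. The Y-linked gene Eif2s3y had a signal of 552 ± 106 in male shams and 741 ± 373 in male TAC, against 9.05 ± 4.27 and 7.42 ± 5.88 in the corresponding female groups. The Y-linked genes Uty and Kdm5d had signals of 239 ± 35 and 224 ± 42 in male shams and of 64.3 ± 42.6 and 54.8 ± 38.0 in female shams. The filter, on the mean log2 signal over all 16 arrays, left out these 3 Y-linked genes. Ddx3y was not measured by a named probe set.

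In males, TAC raised the genes of the fetal cardiac programme and of the extracellular matrix most, and lowered genes of fuel oxidation and ion transport. Myh7, the slow β-myosin heavy chain of the fetal mouse ventricle, rose 19.9-fold, from a signal of 831 ± 46 to 18388 ± 8867 (SD, n = 4; log2 fold change 4.31 ± 0.34 SE, adjusted p = 1.28e-07). Nppa, which encodes atrial natriuretic peptide, rose 5.72-fold, from 5094 ± 1106 to 30022 ± 9771 (adjusted p = 2.88e-06). Postn, which encodes the matricellular protein periostin, rose 7.47-fold, from 813 ± 167 to 6450 ± 2301 (adjusted p = 1.28e-06). Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell 5.83-fold, from 13439 ± 3135 to 2251 ± 210 (adjusted p = 2.18e-05).

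The other largest rises in males were those of the matrix genes Thbs4 (log2 fold change 3.18), Ccn2 (2.79), Ltbp2 (2.62) and Comp (2.58), the collagen receptor gene Mrc2 (2.58), the Wnt antagonist gene Frzb (2.43) and the immediate early gene Egr1 (2.37, and 1.56 without male TAC 5), with adjusted p from 1.11e-05 to 0.00379. On the probe set of highest mean of each gene, the other largest falls were those of the calcium channel subunit gene Cacnb2 (-2.48), the interferon-induced genes Ifit1 (-2.35), Usp18 (-1.88) and Cmpk2 (-1.87), the mitochondrial dehydrogenase gene D2hgdh (-2.16), the potassium channel regulator gene Abcc9 (-2.16), the gluconeogenic gene Fbp2 (-2.03, and -1.32 without male TAC 5), Gdap10 (-1.82) and Ralgapa1 (-1.80), with adjusted p from 3.89e-07 to 0.0129. On other probe sets, looked at after the values were seen, Dsp (-3.13), Rad21 (-2.50), Kat2b (-2.47), Yes1 (-2.38) and Ubr1 (-2.05) fell as far, with adjusted p from 4.11e-06 to 0.00101, while on their probe sets of highest mean these genes did not pass (-0.35, -0.39, 0.05, -0.13 and -0.02). Of these calls only that of Dsp held with the Gapdh ratio as a covariate, and those of Rad21, Yes1 and Ubr1 also ended with the 18S signal. Among the genes fixed beforehand, Nppb (2.08), Acta1 (2.25), Col1a1 (1.63), Col3a1 (1.96) and Timp1 (1.78) rose. Myh6, the adult α-myosin heavy chain, fell by 0.33 (log2), and Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.38, both calls that ended after quantile normalization. The regulator of mitochondrial biogenesis Ppargc1a fell by 0.57 (adjusted p = 0.0338), and 1 of its 4 other probe sets had the opposite sign. Single arrays decided both of the latter calls: Atp2a2 lost its call without male TAC 1 (adjusted p = 0.06), male TAC 2 (0.0623), male sham 3 (0.057) or male sham 4 (0.0692), within a range over its alternatives of 0.00864 to 0.916. Ppargc1a lost its call without male TAC 2 (adjusted p = 0.117), male TAC 4 (0.091) or male sham 1 (0.0585), 2 (0.0811) or 3 (0.103), within a range of 0.0181 to 0.857. Ppara did not pass (-0.49, adjusted p = 0.18), and Esr1, which was below the signal limit, did not pass either (0.63, adjusted p = 0.515).

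Of 11 measured fetal and stretch-response genes, 9 rose in males (10 adjusted over the list alone), with a median log2 fold change of 1.51. The cardiac stress gene Ankrd1 rose by 1.51. Of 17 collagens, 14 rose (15 adjusted over the list alone; median 1.24), Col1a2 by 2.14 and Col5a2 by 2.24. Of 27 matricellular, elastic and proteoglycan matrix genes, 21 rose (22 adjusted over the list alone; median 1.33). Among them were Fstl1 (1.88), the calcification inhibitor gene Mgp (1.66) and the elastin crosslinker gene Loxl1 (2.30). Of 33 genes of the actin and microtubule cytoskeleton, 18 rose (24 adjusted over the list alone; median 0.60), Tuba1a by 1.69 and Actg1 by 1.03. Of 16 fibroblast markers, 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.58). Pi16 changed by 1.40 and Mfap5 by 1.71. The camera calls of these lists held with an estimated correlation (adjusted p = 0.0121, 0.00499, 0.0204, 0.00499 and 0.0477, in the order given). That of the fibroblast markers was lost at the preset correlation with the Gapdh ratio as a covariate.

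Genes of fat and pyruvate oxidation fell in males. Of 24 genes of fatty acid uptake and oxidation, 18 fell (18 adjusted over the list alone; median -0.53). Among them were Etfdh (-0.96), which passes electrons from β-oxidation to the respiratory chain, and the subunits of the trifunctional protein Hadha (-0.95) and Hadhb (-0.63). Of 15 PPAR-responsive genes, 7 fell (12 adjusted over the list alone; median -0.59). Mlycd changed by -1.14 and the mitochondrial carrier gene Ucp3 by -1.62. Of 20 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 13 fell (13 adjusted over the list alone; median -0.39), Dld by -0.82 and Idh3a by -0.79. Of 19 regulators of mitochondrial biogenesis, 3 fell (3 adjusted over the list alone; median -0.30). Tfb2m changed by -0.62. Of 18 genes of calcium handling and ion channels, 9 fell and 2 rose (10 and 2 adjusted over the list alone; median -0.52). Falls included those of the potassium channel subunit gene Kcnip2 (-1.50), Pln (-0.56) and the calcium release channel gene Ryr2 (-0.57). The calls of these lists held with an estimated correlation (adjusted p = 0.000318, 0.00499, 0.00499, 0.0477 and 0.0206). That of the mitochondrial biogenesis regulators was lost at the preset correlation with the Gapdh ratio as a covariate.

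The preset-correlation calls of 12 further lists in males were lost with an estimated correlation. Of 75 genes of oxidative phosphorylation, 17 fell and 1 rose (24 and 1 adjusted over the list alone; median -0.18), Ndufs4 by -0.46 (for the list, adjusted p = 0.0993 with an estimated correlation). Of 40 cytosolic ribosomal proteins, 12 rose (13 rose and 1 fell adjusted over the list alone; median 0.20), Rpl35 by 0.69 (for the list, adjusted p = 0.0993 with an estimated correlation). Of 22 macrophage markers, 7 rose (8 adjusted over the list alone; median 0.51), Ctss and Adgre1 each by 0.83 (for the list, adjusted p = 0.157 with an estimated correlation). Of 17 immediate early genes, 6 rose (8 adjusted over the list alone; median 0.63), Btg2 by 1.95 and Ier5 by 1.43 (for the list, adjusted p = 0.203 with an estimated correlation). The score of this list was 1.41 on male TAC 5 against -0.0678 to 0.0829 on the other male TAC arrays, and its median log2 fold change was 0.35 without that array. Of 23 interferon-responsive genes, 11 fell (15 adjusted over the list alone; median -0.88), Oasl2 by -1.54 and Ifit3 by -1.89 (for the list, adjusted p = 0.164 with an estimated correlation). The calls of oxidative phosphorylation and of the interferon list at the preset correlation ended with the 18S signal as a covariate.

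Of 25 genes of TGF-beta and BMP signalling in males, 8 rose and 2 fell (8 and 3 adjusted over the list alone; median 0.20). Ltbp3 changed by 1.61 and Tgfb2 by 1.70 (for the list, adjusted p = 0.0854 with an estimated correlation). Of 18 matrix proteases and inhibitors, 5 rose and 1 fell, counts that were the same adjusted over the list alone (median 0.18). Timp2 changed by 1.02 and Timp4 by -1.44 (for the list, adjusted p = 0.191 with an estimated correlation). Of 19 cell cycle genes, 6 rose, also adjusted over the list alone (median 0.57), Ccnd1 by 0.74 and Cks2 by 1.67 (for the list, adjusted p = 0.123 with an estimated correlation). Of 14 heat shock proteins, 5 rose and 1 fell, also adjusted over the list alone (median 0.35). Hspb8 changed by 0.37 and Hspd1 by -0.48 (for the list, adjusted p = 0.293 with an estimated correlation). Of 9 genes of sex steroid reception and metabolism, 5 fell (6 adjusted over the list alone; median -0.44). The steroid dehydrogenase gene Hsd17b11 changed by -0.49 and the coactivator gene Ncoa4 by -0.44 (for the list, adjusted p = 0.0562 with an estimated correlation). Of 11 clock genes, 2 fell (4 adjusted over the list alone; median -0.49), the repressors Nr1d2 (-1.12) and Nr1d1 (-1.01) (for the list, adjusted p = 0.211 with an estimated correlation). Of 19 sarcomere genes of the adult ventricle, 5 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.20). Nebl changed by -1.74 and Tnni3 by -0.39 (for the list, adjusted p = 0.449 with an estimated correlation). The direction of this list relative to the other genes, and the sign of its median, turned with the 18S signal as a covariate (0.04, adjusted p = 0.551). At the preset correlation the sarcomere list lost its call without male TAC 4 (adjusted p = 0.0769) or male sham 4 (0.0506), the proteases without male TAC 5 (0.0688) or male sham 1 (0.0667), and the heat shock proteins without male TAC 5 (0.0896) or male sham 1 (0.082). The TGF-beta list lost its call without male TAC 4 (0.0769), male TAC 5 (0.0639), male sham 2 (0.0504) or male sham 3 (0.053). The median of the TGF-beta list was 0.13 without male sham 1 or 3, and that of the heat shock proteins 0.22 without male sham 1. The calls of the TGF-beta list, the clock genes and the sarcomere ended with either quality covariate, and those of the proteases and the heat shock proteins with the Gapdh ratio. Over all alternatives at the preset correlation the adjusted p ranged from 0.00067 to 0.721 for the sarcomere list, from 0.00759 to 0.498 for the proteases, from 0.000166 to 0.0896 for the heat shock proteins and from 0.0232 to 0.157 for the TGF-beta list.

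**Figure D1:**
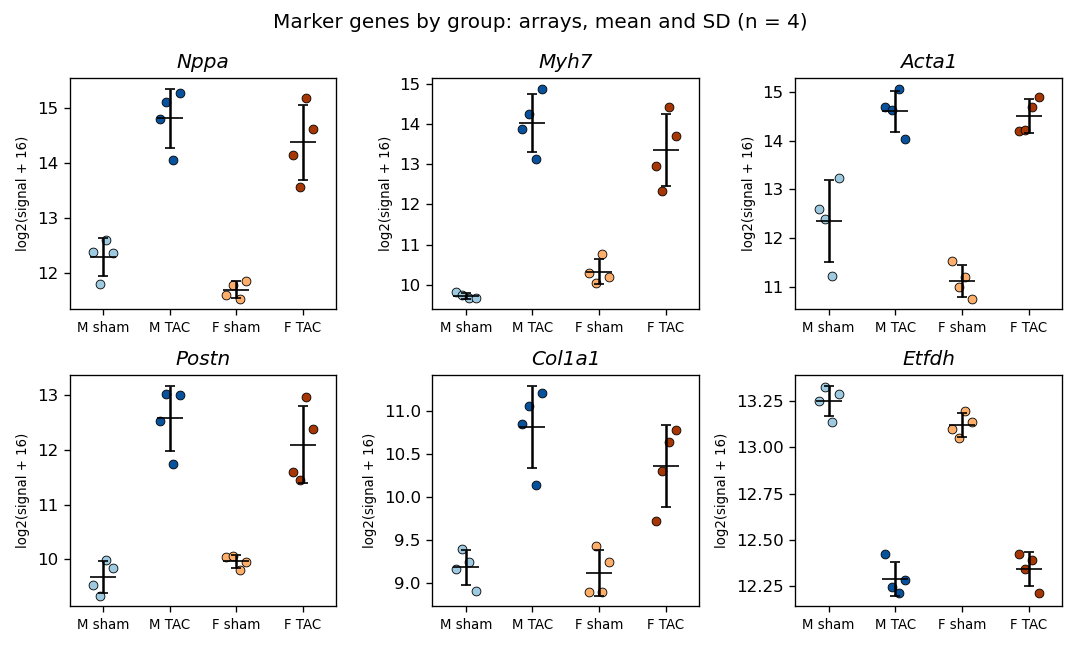
Signals of the fetal genes Nppa, Myh7 and Acta1, the matrix genes Postn and Col1a1 and the fatty acid oxidation gene Etfdh as log2(signal + 16) on the y axis, by group on the x axis (M, male; F, female). Points are single arrays, and the horizontal marks with bars are the mean and SD of 4 arrays. Etfdh was lower by 0.96 in male TAC and by 0.78 in female TAC (log2), and the other genes were higher in both TAC groups.

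In males, limma called 2422 of 13576 probe sets, for 1803 genes, of which 1095 rose and 1327 fell, with 602 changed at least 2-fold (260 higher, 342 lower). After median centring 1246 of 2277 calls were higher, 54.7% against 45.2%, so the balance of rises and falls depended on the scaling. The signals of the groups did not overlap for 2666 probe sets (19.6%), where chance gives 2.86%. With the 18S signal as a covariate 997 probe sets were called and with the Gapdh ratio 398, and 4 and 12 of the 20 genes named for the largest changes lost their call.

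In females, TAC also raised fetal cardiac genes and matrix genes most. Acta1, the skeletal α-actin of the fetal heart, rose 10.4-fold, from a signal of 2251 ± 530 to 23615 ± 5684 (SD, n = 4; log2 fold change 3.38 ± 0.30 SE, adjusted p = 5.15e-07). Myh7 rose 8.20-fold, from 1288 ± 298 to 12121 ± 7447 (adjusted p = 8.08e-06), and Nppa 6.36-fold, from 3333 ± 360 to 23014 ± 10589 (adjusted p = 2.36e-06). Tnfrsf12a, the receptor for the cytokine TWEAK, rose 7.10-fold, from 493 ± 59 to 3612 ± 514 (adjusted p = 1.18e-07). Nebl, which encodes the Z-disc protein nebulette, fell 4.78-fold, from 328 ± 79 to 55.5 ± 14.0 (adjusted p = 1.98e-05).

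Other large rises in females were those of Thbs4 (3.05), Ccn2 (2.34), Ltbp2 (2.27, and 1.67 without female TAC 3), Postn (2.14) and the cell cycle inhibitor gene Cdkn1a (2.01), with adjusted p from 4.73e-05 to 0.00364. On the probe set of highest mean of each gene, the other largest falls were those of D2hgdh (-2.19), Abcc9 (-2.16), Cacnb2 (-1.92), Fbp2 (-1.87), Asb15 (-1.83), the galectin gene Lgals4 (-1.67), Ano10 (-1.55), Magi3 (-1.50) and the carboxylesterase gene Ces1d (-1.49), with adjusted p from 5.15e-07 to 0.0274. On other probe sets, looked at after the values were seen, Dio2 (2.74) and Nupr1 (2.39) rose and Nampt (-2.13), Ssr4 (-2.13), Otud4 (-2.08), Dbp (-2.08), Gja1 (-2.06), Rad21 (-2.05) and Ide (-2.04) fell, with adjusted p from 5.15e-07 to 0.00767. On their probe sets of highest mean Nampt fell as well (-0.92), and the others did not pass (0.39, 1.03, -0.07, -0.33, -1.66, 0.09, -0.33 and -0.32, in the order given). The calls of Dio2, Nupr1, Dbp and Rad21 ended with the Gapdh ratio as a covariate and that of Ssr4 with the 18S signal. Fbp2 and Ces1d lost their calls without female TAC 3 (adjusted p = 0.0941 and 0.106), without female TAC 5 (0.0663 and 0.0864) and without female sham 1 (0.0528 and 0.0558), 2 (0.0513 and 0.0501) or 3 (0.0529 and 0.069), and over all their alternatives their adjusted p ranged from 0.00069 to 0.139 and from 0.00422 to 0.141. Nppb (1.86), Col1a1 (1.24), Col3a1 (0.91) and Timp1 (1.66) rose. Myh6 fell by 0.37 and Atp2a2 fell by 0.51, both calls that ended after quantile normalization. Ppargc1a (-0.32, adjusted p = 0.269), Ppara (-0.05, adjusted p = 0.931, with a positive sign after median centring and without female TAC 3, female TAC 5 or female sham 4, at 0.04, 0.19 and 0.04), Esr1 (-0.40, adjusted p = 0.718) and Xist (0.48, adjusted p = 0.0658) did not pass.

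Of 11 fetal and stretch-response genes, 10 rose in females (10 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.36, and Ankrd1 rose by 1.46. Of 17 collagens, 13 rose (15 adjusted over the list alone; median 0.91), Col1a2 by 1.67 and Col5a1 by 1.21. Of 18 matrix proteases and inhibitors, 7 rose, also adjusted over the list alone (median 0.42). Mmp2 changed by 1.04 and Adam15 by 0.76. Of 33 cytoskeletal genes, 15 rose (22 adjusted over the list alone; median 0.43). Tubb2a changed by 1.90 and the actin-binding protein gene Pfn1 by 0.99. The calls of these 4 lists held with an estimated correlation (adjusted p = 0.0134, 0.0134, 0.0325 and 0.0115). Of 27 matricellular, elastic and proteoglycan matrix genes, 18 rose (20 rose and 1 fell adjusted over the list alone; median 1.07). Pcolce changed by 1.28 and Bgn by 1.22 (for the list, adjusted p = 0.0569 with an estimated correlation).

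Of 24 genes of fatty acid uptake and oxidation, 18 fell in females (20 adjusted over the list alone; median -0.50). Etfdh changed by -0.78, Acaa2 by -0.97 and Hadha by -0.86. Of 15 PPAR-responsive genes, 9 fell (10 adjusted over the list alone; median -0.60). Ucp3 changed by -1.40 and the lipid droplet gene Plin5 by -0.73. Of 20 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 10 fell (13 adjusted over the list alone; median -0.35). Suclg2 changed by -1.03 and Idh3a by -0.76. Of 18 genes of calcium handling and ion channels, 9 fell and 1 rose (11 and 2 adjusted over the list alone; median -0.41). Falls included those of Pln (-0.60) and Kcnip2 (-1.40). The calls of these lists held with an estimated correlation (adjusted p = 0.000366, 0.0134, 0.0134 and 0.0291).

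Further list calls in females were lost with an estimated correlation. Of 75 genes of oxidative phosphorylation, 15 fell and 2 rose (20 and 2 adjusted over the list alone; median -0.16). Ndufs1 changed by -0.70 (for the list, adjusted p = 0.153 with an estimated correlation). Of 22 macrophage markers, 3 rose (4 adjusted over the list alone; median 0.30). Csf1r changed by 0.64 and Mpeg1 by 1.81 (for the list, adjusted p = 0.282 with an estimated correlation). Of 14 heat shock proteins, 5 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.35). Hspb8 changed by 0.59 and Hspa8 by 0.93 (for the list, adjusted p = 0.128 with an estimated correlation). Of 17 immediate early genes, 5 rose, also adjusted over the list alone (median 0.49). Atf3 changed by 1.74 (for the list, adjusted p = 0.298 with an estimated correlation). Of 19 cell cycle genes, 4 rose (6 adjusted over the list alone; median 0.43). Mcm2 changed by 1.30 and the inhibitor gene Cdkn1a by 2.01 (for the list, adjusted p = 0.298 with an estimated correlation). Of 12 glucocorticoid-responsive genes, 5 rose and 1 fell, also adjusted over the list alone (median 0.65). Mt2 changed by 1.39, Ddit4 by 1.69 and Klf9 by -0.88 (for the list, adjusted p = 0.395 with an estimated correlation). Of 11 clock genes, 4 fell (6 adjusted over the list alone; median -0.70). Nr1d2 changed by -1.02 and Nr1d1 by -1.03 (for the list, adjusted p = 0.19 with an estimated correlation). Among the TAC arrays male TAC 4 and female TAC 1 stood apart in Arntl, with a signal of 32.9 and 22 against 325.9 to 538.4 on the others, but female TAC 1 did not in Nr1d1 (384.4 against 290.3 to 660.2 on the others). The highest clock scores were 0.161 in male TAC and 0.119 in female TAC, near the lowest sham scores of 0.196 in males and 0.194 in females. Of 16 fibroblast markers, 4 rose, also adjusted over the list alone (median 0.25). Pi16 changed by 1.37 and Meox1 by 1.32 (for the list, adjusted p = 0.37 with an estimated correlation). Of 19 sarcomere genes, 9 fell and 2 rose (9 and 3 adjusted over the list alone; median -0.20). Des, which encodes desmin, changed by 0.61 (for the list, adjusted p = 0.457 with an estimated correlation). Of 9 genes of sex steroid reception and metabolism, 2 fell (6 fell and 1 rose adjusted over the list alone; median -0.35). Hsd17b10 changed by -0.43 (for the list, adjusted p = 0.171 with an estimated correlation). At the preset correlation the sarcomere list lost its call without female TAC 1 (adjusted p = 0.0571) or 2 (0.0938), the cell cycle genes without female TAC 5 (0.0727) or female sham 3 (0.0631), the glucocorticoid-responsive genes without female TAC 3 (0.073), and the sex steroid list without female sham 2 (0.0595) or 4 (0.0557). The fibroblast markers lost theirs without male TAC 1 (0.0571), male TAC 5 (0.051), male sham 3 (0.051), male sham 4 (0.0516), female TAC 2 (0.0838), female TAC 5 (0.11) or female sham 1 (0.0516), 2 (0.0506) or 3 (0.0917). The median moved to -0.12 for the sarcomere list without female TAC 1, 0.19 for the macrophage markers without female TAC 5, 0.55 for the heat shock proteins without female TAC 3 and 0.13 for the fibroblast markers without female sham 3. For the glucocorticoid-responsive genes it was 0.27 without female TAC 3 and 1.0 without female TAC 5. The calls of the sarcomere list and the fibroblast markers ended with either quality covariate, and those of the clock genes and the sex steroid list with the Gapdh ratio. Over all alternatives at the preset correlation the adjusted p ranged from 0.000791 to 0.849 for the sarcomere list, from 0.000473 to 0.268 for the cell cycle genes, from 1.10e-05 to 0.073 for the glucocorticoid-responsive genes, from 0.00785 to 0.0698 for the sex steroid list and from 0.0189 to 0.574 for the fibroblast markers.

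In females, limma called 2045 probe sets, for 1551 genes, of which 877 rose and 1168 fell, with 474 changed at least 2-fold (187 higher, 287 lower), and the groups did not overlap for 2695 probe sets (19.9%, where chance gives 2.86%). The Gapdh ratio as a covariate left 498 calls and the clock gene difference 1288, and 8 of the 20 genes that the rule takes for the largest changes lost their call with the Gapdh ratio. Median centring moved the median log2 fold change of all probe sets from -0.0309 to 0.0847 and the share of calls that were higher from 42.9% to 64.4%, so the balance of rises and falls holds only relative to the scaling used.

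Averaged over the sexes, 20 of the 24 genes of fatty acid uptake and oxidation fell (21 adjusted over the list alone; median -0.49), 10 of the 11 fetal and stretch-response genes rose (10 adjusted over the list alone; median 1.49), and 15 of the 17 collagens rose (15 adjusted over the list alone; median 1.05). The matricellular list (21 of 27 rose, median 1.25), the cytoskeleton (27 of 33 rose, median 0.47), the tricarboxylic acid cycle (15 of 20 fell, median -0.36), the PPAR-responsive genes (11 of 15 fell, median -0.63) and calcium handling and ion channels (11 fell and 2 rose of 18, median -0.45) moved likewise. The 8 lists held with an estimated correlation, with adjusted p from 0.0003 to 0.0309, and 13 other called lists did not. limma called 3890 probe sets, 1747 higher and 2143 lower, for 2794 genes. The 18S signal as a covariate left 1917 calls and the Gapdh ratio 640, and median centring moved the share of calls that were higher from 44.9% to 60.3%.

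**Figure D2:**
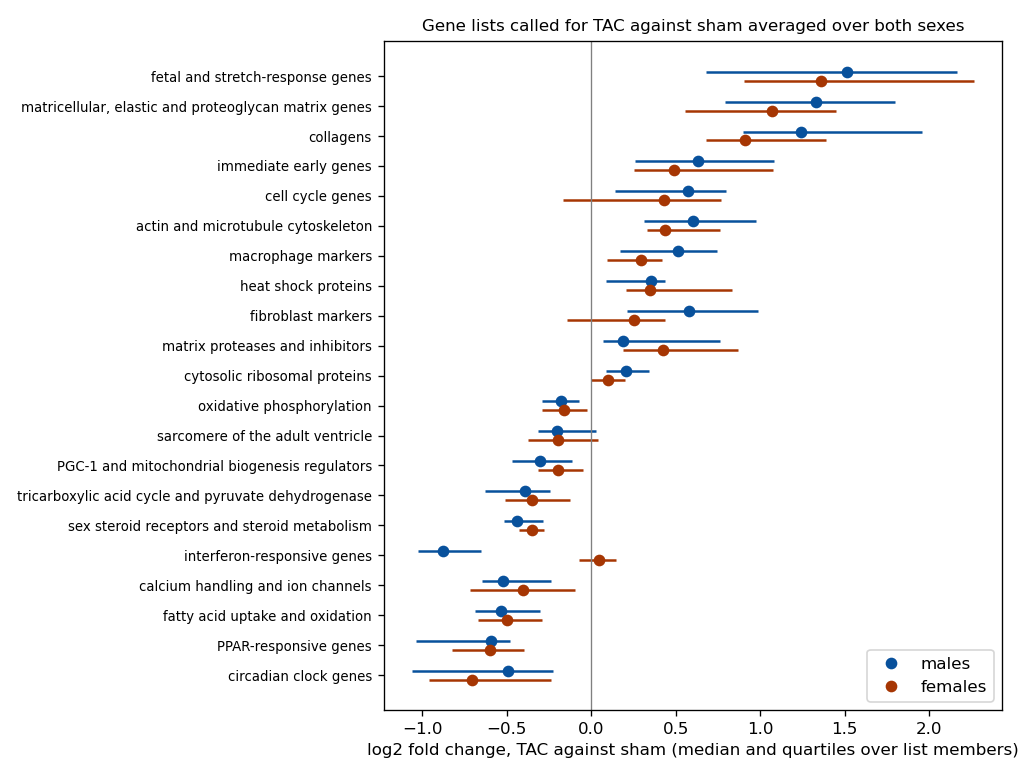
Log2 fold change of TAC against sham on the x axis for the 21 gene lists called for the average over the sexes, by name on the y axis. Points are the medians over the measured members of a list and bars run from the lower to the upper quartile, in males and in females. The fetal and stretch-response genes had medians of 1.51 and 1.36, the fatty acid list had medians of -0.53 and -0.50, and the interferon list had medians of -0.88 in males and 0.05 in females.

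The responses of the sexes overlapped. Of the probe sets called in both, 535 rose in both and 762 fell in both, where independent lists would share 70.7 and 114, and 2 were called in opposite directions. Among the probe sets called in males, 95.3% had the same sign in females, and among those called in females, 97.0% had the same sign in males. The log2 fold changes correlated across all 13576 probe sets with r = 0.666 and rho = 0.613. There were 1123 probe sets called in males and not in females, and 746 called in females and not in males, which by itself does not show that the responses differed.

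**Figure D3:**
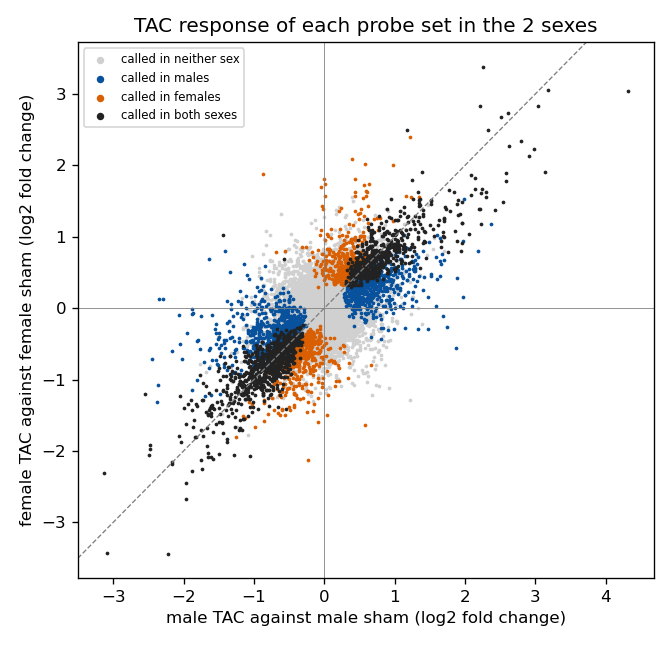
Log2 fold change of TAC against sham of each of 13576 probe sets in males on the x axis and in females on the y axis, coloured by the sex in which the probe set was called. The dashed line marks equal responses. Of the probe sets called in both sexes, 535 lie in the upper right and 762 in the lower left quadrant, with 2 elsewhere.

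No gene passed the test of the difference between the responses. Timp4, an inhibitor of matrix metalloproteinases, came closest (log2 difference, female minus male response, 2.46 ± 0.40 SE, adjusted p = 0.0803): its signal went from 1235 ± 69 in male shams to 466 ± 165 in male TAC, and from 333 ± 139 in female shams to 681 ± 231 in female TAC (SD, n = 4). The interferon-induced genes Trim30a (1.84, adjusted p = 0.0843) and Ifit1 (2.47, adjusted p = 0.216), the steroid sulfate transporter gene Slc10a6 (1.32, adjusted p = 0.255) and the cell cycle regulator gene Rgcc (1.27, adjusted p = 0.284) followed in the same direction. In the other direction stood the cytokine gene Il1b (-1.24, adjusted p = 0.216), the proteoglycan gene Lum (-1.07, adjusted p = 0.216), the collagen gene Col3a1 (-1.05, adjusted p = 0.285), Itih5 (-1.14, adjusted p = 0.285) and Dab2 (-0.90, adjusted p = 0.338), whose 2 other probe sets had the opposite sign. The difference was -1.28 for Myh7 and 1.13 for Acta1 (adjusted p = 0.664 for each).

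At the preset correlation, camera called 6 lists for the difference of responses, and with an estimated correlation or with fry 0 were called. All but the matricellular list were also called between the shams at the preset correlation, in the opposite direction and on the same sham arrays. The interferon-responsive genes had a median difference of 1.01 (0 of 23 members past the threshold, 12 higher adjusted over the list alone). The difference for Usp18 was 1.87 (for the list, adjusted p = 0.525 with an estimated correlation). The glucocorticoid-responsive genes had a median of 0.80 (0 of 12 past the threshold, 3 higher adjusted over the list alone). The difference for Mt2 was 1.41 (for the list, adjusted p = 0.525 with an estimated correlation). The collagens (-0.39), the matricellular list (-0.30), the ribosomal proteins (-0.15) and the fibroblast markers (-0.14) had negative medians, with 1, 1, 0 and 5 members lower adjusted over the list alone (adjusted p = 0.563, 0.563, 0.563 and 0.525 with an estimated correlation). At the preset correlation the collagens lost their call without male TAC 2 (adjusted p = 0.101) or female TAC 1 (0.163), the ribosomal proteins without female TAC 2 (0.0883) or male sham 2 (0.0975), and the fibroblast markers without male TAC 2 (0.0693). The median moved to -0.20 for the collagens without female TAC 1, -0.18 for the matricellular list without male TAC 2 and 0.48 for the glucocorticoid-responsive genes without female TAC 3. That of the fibroblast markers was -0.08 without male TAC 2, -0.29 without male TAC 4, -0.22 without male TAC 5 and -0.22 without male sham 4. The calls of the collagens and the fibroblast markers ended with the Gapdh ratio as a covariate. Over all alternatives at the preset correlation the adjusted p ranged from 0.000116 to 0.239 for the collagens, from 0.000134 to 0.0975 for the ribosomal proteins and from 4.88e-05 to 0.118 for the fibroblast markers.

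limma called 0 of 13576 probe sets for the difference of responses, with 897 at an unadjusted p below 0.05, and on simulated data the same test recovered 78.8% of log2 differences of 2 and 38.8% of those of 1. Without male TAC 5, 11 probe sets passed, among them those of Timp4 (adjusted p = 0.0266), Trim30a (0.0266) and Ifit1 (0.00487), whose adjusted p over all alternatives ranged from 0.00994 to 0.281, from 0.0092 to 0.308 and from 0.00487 to 0.511, and 3 passed without female TAC 5 and 1 each without male TAC 1, male sham 2 or female sham 4. Timp4 passed without female TAC 5 (0.00994), male TAC 1 (0.0332) or female sham 4 (0.0183) and Trim30a without male sham 2 (0.0092).

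Among the shams, several interferon-responsive genes were lower in females than in males. Ifit1 was 5.30-fold lower, with a signal of 2307 ± 850 in male shams and 399 ± 42 in female shams (SD, n = 4; adjusted p = 0.00234), against 493 ± 357 in male TAC and 446 ± 121 in female TAC. Ifit3 was 4.62-fold lower (2687 ± 1089 against 526 ± 30, adjusted p = 0.00325), and Timp4 was 3.82-fold lower (adjusted p = 0.00234). Of 23 interferon-responsive genes, 9 were lower in female shams (21 adjusted over the list alone; median -1.16; adjusted p = 0.0532 with an estimated correlation, 0.00813 with fry). The fall of these genes after TAC in males, the difference of responses and this comparison use the same 4 male sham arrays and are not independent of one another.

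The other named genes lower in female shams were Ifit2 (-2.55), Usp18 (-1.94), Cmpk2 (-1.80), Trim30a (-1.67), the antiviral gene Oasl2 (-1.53), Bst2, which encodes tetherin (-1.41), and Trim34a (-1.39), with adjusted p from 0.00104 to 0.0192. Higher in female shams were Xist (3.56), the X-linked genes Ddx3x (0.72) and Eif2s3x (0.71), Itih5 (1.26), Lum (0.88), the cytoplasmic actin gene Actg1 (0.73) and Dab2 (0.76), with adjusted p from 8.77e-11 to 0.0199, each on its probe set of highest mean. On other probe sets, looked at after the values were seen, Cks2 (1.77), the vimentin gene Vim (0.69) and the survival gene Mcl1 (0.67) were higher, with adjusted p from 0.0111 to 0.027, while on their probe sets of highest mean they did not pass (0.99, 0.53 and 0.28). Cks2 lost this call without male sham 1 (adjusted p = 0.0807), 2 (0.0725) or 3 (0.109) or female sham 1 (0.105), 2 (0.0942) or 4 (0.0847), and Mcl1 without male sham 3 (0.0848) or 4 (0.0561) or female sham 1 (0.0963) or 2 (0.0796). Over all alternatives the adjusted p of these probe sets ranged from 0.00426 to 0.23 for Cks2, from 0.00733 to 0.0645 for Vim and from 0.0117 to 0.0963 for Mcl1. The 2 other probe sets of Dab2 had the opposite sign. Several of these calls were lost when 1 sham array was left out: those of Lum without male sham 3 (adjusted p = 0.0541) or 4 (0.0501), Actg1 without male sham 3 (0.0576), Eif2s3x without male sham 3 (0.0541), male sham 4 (0.0657) or female sham 1 (0.0696), and Dab2 without male sham 3 (0.0938), male sham 4 (0.0657), female sham 1 (0.107) or female sham 4 (0.0848). Cmpk2 lost its call without male sham 3 (0.0865), male sham 4 (0.0825) or female sham 1 (0.0511), 2 (0.0734) or 4 (0.0618), and Bst2 without male sham 1 (0.0759), 3 (0.0822) or 4 (0.0696) or female sham 2 (0.0624) or 3 (0.0542). Over all alternatives the highest adjusted p of these 6 genes was 0.0595 for Lum, 0.0645 for Actg1, 0.0696 for Eif2s3x, 0.107 for Dab2, 0.118 for Cmpk2 and 0.103 for Bst2, and the lowest were 0.00227, 0.00247, 0.0066, 0.0107, 0.00197 and 0.00348. Of 5 sex chromosome genes, 3 were higher in female shams on their probe sets of highest mean (4 adjusted over the list alone), the one list of this comparison that held with an estimated correlation (adjusted p = 0.00266).

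At the preset correlation 10 more lists were called between the shams, none of which held with an estimated correlation. The glucocorticoid-responsive genes (median -0.57), the tricarboxylic acid cycle (-0.11), fatty acid oxidation (-0.09), the sarcomere (-0.09) and oxidative phosphorylation (-0.07) were lower in females, with 0 members past the threshold in each and with 2, 1, 0, 0 and 0 adjusted over the list alone (adjusted p = 0.346, 0.345, 0.345, 0.564 and 0.444 with an estimated correlation). The cell cycle genes (median 0.36), fibroblast markers (0.18), cytoskeleton (0.16), collagens (0.14) and ribosomal proteins (0.11) were higher, with 0, 1, 1, 0 and 0 members past the threshold on the probe set of highest mean of each gene and 1, 5, 6, 1 and 0 adjusted over the list alone (adjusted p = 0.345, 0.345, 0.345, 0.432 and 0.346 with an estimated correlation). At the preset correlation single sham arrays decided the calls of 6 of these lists. The sarcomere call was lost without male sham 1 (adjusted p = 0.11), 3 (0.0651) or 4 (0.186) or female sham 1 (0.0639), 2 (0.0724) or 4 (0.0549), and the fatty acid oxidation call without male sham 1 (0.056), 2 (0.0573), 3 (0.0518) or 4 (0.0845) or female sham 2 (0.127), 3 (0.109) or 4 (0.0771). The tricarboxylic acid cycle call was lost without male sham 1 (0.056), male sham 3 (0.0518) or female sham 4 (0.0705), the oxidative phosphorylation call without male sham 4 (0.179) or female sham 4 (0.0889), the collagen call without male sham 2 (0.0601), female sham 2 (0.0534) or female sham 4 (0.0681), and the ribosomal call without male sham 2 (0.0619). Without single arrays the medians moved to -0.05 for the sarcomere (without male sham 1 or 4), -0.04 for fatty acid oxidation (female sham 2) and 0.05 or 0.06 for the ribosomal proteins (male sham 2, female sham 4). They moved to 0.31, 0.05 or 0.28 for the collagens (male sham 1, male sham 3, female sham 2) and 0.06 or 0.09 for the cytoskeleton (male sham 2, female sham 2). The calls of the glucocorticoid-responsive genes, the tricarboxylic acid cycle, fatty acid oxidation, the sarcomere and oxidative phosphorylation also ended with the 18S signal as a covariate. For the sarcomere the direction relative to the other genes then turned (adjusted p = 0.966), while its median stayed below 0 (-0.03). Over all alternatives at the preset correlation the adjusted p ranged from 0.00119 to 0.966 for the sarcomere list, from 0.0119 to 0.246 for fatty acid oxidation, from 0.00895 to 0.297 for the tricarboxylic acid cycle, from 0.00357 to 0.852 for oxidative phosphorylation, from 0.000636 to 0.0681 for the collagens and from 4.88e-05 to 0.0619 for the ribosomal proteins.

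**Figure D4:**
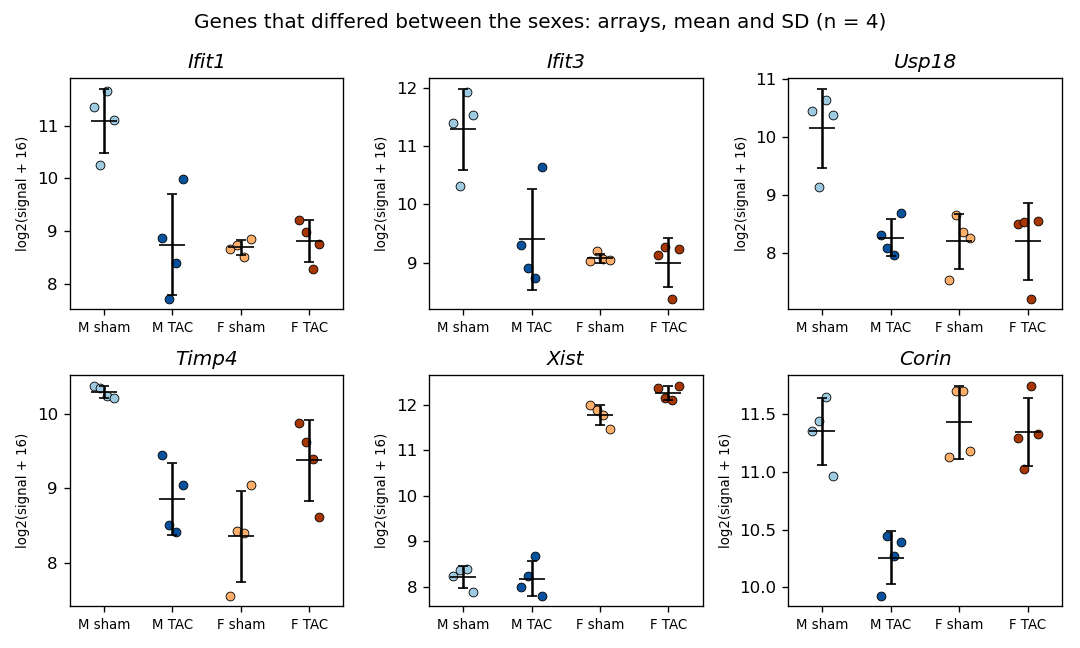
Signals of the interferon-induced genes Ifit1, Ifit3 and Usp18, of Timp4, Xist and Corin as log2(signal + 16) on the y axis, by group on the x axis (M, male; F, female). Points are single arrays, and the horizontal marks with bars are the mean and SD of 4 arrays. The interferon genes and Timp4 were highest in the male shams, where Ifit1 had a mean signal of 2307, and Corin was lowest in male TAC, at 1219.

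Between the shams limma called 42 probe sets, and 1424 had an unadjusted p below 0.05. Of the 42, 13 were higher and 29 lower in females, with 6 on the X chromosome, 30 on autosomes, 2 without a symbol and 4 with several symbols. The count was 17 without male sham 3, 25 without male sham 4, 27 without female sham 1, 69 without male TAC 5, 26 with the 18S signal as a covariate, 21 without an intensity trend and 88 with the sham arrays alone. Of the 17 genes named for the largest differences, 6 lost their call with the 18S signal as a covariate (Lum, Dab2, Eif2s3x, Usp18, Cmpk2 and Bst2) and 6 without an intensity trend (Lum, Dab2, Actg1, Eif2s3x, Cmpk2 and Bst2). Those of Cks2 and Mcl1 on other probe sets ended with the 18S signal as well. Without male sham 3 the calls of Ifit2 (adjusted p = 0.053), Usp18 (0.0527) and Trim34a (0.0527) were lost, within ranges over the alternatives of 0.000561 to 0.053, 0.00073 to 0.058 and 0.00259 to 0.0527.

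After TAC, 6 genes with a name differed between the sexes. Xist was 17.0-fold higher in females (adjusted p = 6.35e-12), and Corin, which encodes the protease that activates atrial natriuretic peptide, was 2.13-fold higher (log2 difference 1.09 ± 0.18 SE, adjusted p = 0.0112). The signal of Corin was 1219 ± 187 in male TAC and 2629 ± 567 in female TAC, against 2630 ± 509 in male shams and 2789 ± 607 in female shams (SD, n = 4). Pxn, which encodes the focal adhesion protein paxillin, was 1.59-fold higher in females (adjusted p = 0.0379), with a signal of 1555 ± 114 against 979 ± 120. On probe sets other than that of highest mean, looked at after the values were seen, the X-linked genes Kdm6a (2.32-fold), Eif2s3x (1.88-fold) and Ddx3x (1.73-fold) were also higher in females, with adjusted p of 0.0151, 0.00445 and 0.00445. On their probe sets of highest mean these genes did not pass (log2 difference 0.29, 0.62 and 0.54). Kdm6a lost its call without male TAC 1 (adjusted p = 0.0746) or 2 (0.0728) or female TAC 1 (0.0869), 2 (0.0682) or 3 (0.0878). Over all alternatives the adjusted p ranged from 0.00407 to 0.437 for Kdm6a, from 0.00114 to 0.112 for Eif2s3x and from 6.20e-05 to 0.224 for Ddx3x, and with the TAC arrays alone none of them passed.

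Of 5 sex chromosome genes, 1 was higher in female TAC on its probe set of highest mean (4 adjusted over the list alone; adjusted p = 0.00056 with an estimated correlation). The interferon-responsive genes had a median difference of -0.23 in TAC and were not called. The matricellular list (median -0.25) and the sarcomere list (median -0.11) were called at the preset correlation with 0 members past the threshold (adjusted p = 0.719 for each with an estimated correlation). The matricellular call was lost with the Gapdh ratio as a covariate and without male TAC 5 (adjusted p = 0.0556), and the sarcomere call without male TAC 5 (0.576), female TAC 1 (0.059), female TAC 2 (0.386) or female sham 4 (0.0522). The median of the sarcomere list moved to -0.04 without male TAC 5, -0.04 without female TAC 2 and -0.16 without female TAC 3, and that of the matricellular list to -0.42 without male TAC 4, -0.14 without female TAC 1 and -0.38 without female TAC 3. Over all alternatives at the preset correlation the adjusted p ranged from 3.74e-11 to 0.304 for the matricellular list and from 7.56e-05 to 0.72 for the sarcomere list.

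Between the TAC groups limma called 9 probe sets, 8 higher and 1 lower in females, and 874 had an unadjusted p below 0.05. Of the 9, 5 lay on the X chromosome, 2 on autosomes and 2 had no symbol, and 5 were also called between the shams. Of 35 splits of the TAC arrays, the real one included, 6 gave at least 2 calls on autosomes. The call of Corin was lost without male TAC 1 (adjusted p = 0.0746) and without female TAC 3 (0.0638), with a range over all alternatives of 0.00574 to 0.107. It was also lost with the Gapdh ratio as a covariate, without an intensity trend, with the TAC arrays alone and without male TAC 4 and female TAC 1 together. The call of Pxn was lost in 19 of 31 alternatives, with a range of 0.0222 to 0.353. Pxn lost its call without male TAC 1 (0.0898), 2 (0.19) or 4 (0.123), female TAC 1 (0.0869), 2 (0.0873), 3 (0.0926) or 5 (0.152), male sham 1 (0.0555) or 2 (0.0542), or female sham 2 (0.0633) or 3 (0.0607).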

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

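The tests on interferon genes, on the time of day and on array quality were chosen after the result was seen, and their criteria were changed once their values were known, and the counts over splits of autosomal calls, of lists with an estimated correlation and of lists other than the sex chromosome list were also chosen after; the other counts over splits and the relation of clock to fetal genes were fixed before their results.

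In 400 groups of 4 arrays, made of list scores, array measures and the genes named by rule, 28 single arrays lay far from the other 3 of their group, where chance gives about 1 in 20 groups, or 20. Other members of the lists were not searched one by one. Male TAC 5 and female TAC 3 stood out most often, 5 times each. On male TAC 5 the 18S signal was 13.2 (log2), the score for immediate early genes 1.41 against -0.0678 to 0.0829 on the other male TAC arrays, for glucocorticoid-responsive genes 0.604 and for the proteasome 0.0689, and the Ppara signal 9.68 (log2). Female TAC 3 had an interferon score of -0.856 against -0.204 to -0.0986, with Usp18 at 7.22 and Ifit3 at 8.38, an angiogenesis score of 0.293 and Slc10a6 at 9.36. The macrophage score was 0.222 on male sham 1 and 0.347 on female TAC 5, and female TAC 5 also had a calcium handling score of -0.053 and Pxn at 10.8. Female sham 1 had an immediate early score of -0.691, Atp2a2 at 15.8 and Ppargc1a at 10.6. Female TAC 2 had an oxidative phosphorylation score of -0.142 and Atp2a2 at 14.7, and female TAC 1 had Frzb at 8.22 and D2hgdh at 7.83. Female sham 4 had Fbp2 at 9.31 and Actg1 at 12.8, female sham 3 had Lum at 10.9, and female sham 2 had a score of 0.0748 for mitochondrial biogenesis regulators. Male sham 4 had a sex chromosome score of -0.675 and Ccn2 at 9.81, and male sham 2 had Egr1 at 8.79.

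For 6 gene lists the response to TAC differed between the sexes by camera at its preset correlation, female minus male: the interferon-responsive genes by a median of 1.01, the glucocorticoid-responsive genes by 0.8, the collagens by -0.393, the matricellular list by -0.301, the ribosomal proteins by -0.151 and the fibroblast markers by -0.142. None of the 6 differed with an estimated correlation or with fry. At the preset correlation all but the matricellular list were also called between the shams, in the opposite direction. The score of the ribosomal proteins was -0.130 in male and -0.027 in female shams, and 0.089 and 0.068 in TAC. That of the glucocorticoid-responsive genes was 0.134 and -0.444 in shams, and 0.013 and 0.297 in TAC. The same sham arrays enter both comparisons, so these differences of responses can reflect the shams.

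Other splits of the same arrays gave fewer called probe sets in each comparison except the difference of responses. In males 1 of 35 splits, the real one, gave 2422 calls and the highest other gave 42. In females 1 of 35 gave 2045 and the highest other 2, and averaged over the sexes 1 of 100 gave 3890 and the highest other 10. Between the shams 1 of 35 gave 42 and the highest other 1, and between the TAC groups 1 of 35 gave 9 and the highest other 7. A share of 1 of 35 is the lowest that 35 splits allow, and the counts were not adjusted for their number. The counts for TAC against sham in males, in females and averaged lay far above any other split, which argues against chance for them. Between the shams the margin was wide as well. However, 9 of the 42 calls there were members of the interferon list, whose genes can move together. The count was 17 without male sham 3. That margin therefore adds little to the share of 1 of 35, and chance is not excluded for the sham count. Of the 9 calls between the TAC groups 5 lay on the X chromosome, so the real split had to rank high and that count does not exclude chance. Genes on the sex chromosomes tell the sexes apart by themselves. On autosomes alone 1 of 35 splits gave 30 calls between the shams and the highest other 1, a margin under the same limit. Between the TAC groups 6 of 35 gave the real count of 2 or more and the highest other 7. Chance cannot be excluded for a difference of autosomal genes there either. For the difference of responses the real count was 0, which all 100 of 100 splits reach by construction, with a highest count of 18, so this count cannot be tested in this way. For the counts of called lists the real split ranked first in males (1 of 35, 22 lists against at most 17), for the average (1 of 100, 21 against at most 19) and between the shams (1 of 35, 12 against at most 10, and without the sex chromosome list 1 of 35, 11 against at most 9). These margins were small, so chance is not excluded for these counts. Nor can it be excluded in females (3 of 35, 19 against 19), for the difference (34 of 100, 6 against 14) or between the TAC groups (34 of 35, 3 against 14, and without the sex chromosome list 35 of 35, 2 against 14). For the difference the splits shuffled sex within each operation, which also broke up sex differences present with either operation, such as that of Xist. The counts of those splits are therefore not a plain chance level. At its preset correlation camera thus called many lists in arbitrary splits. With an estimated correlation 1 of 35 splits gave 10 lists in males (highest other 1), 1 of 35 gave 8 in females (0) and 1 of 100 gave 8 for the average (1), which argues against chance for these counts. The 1 list between the shams (1 of 35, highest other 0) and the 1 between the TAC groups (4 of 35, highest other 2) were the sex chromosome list, which tells the sexes apart by itself. Without it both counts were 0 (highest other 0 and 2), which 35 of 35 splits reach, as 100 of 100 (highest other 2) reach the 0 for the difference, so none of these counts can be tested in this way.

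Of 23 interferon-responsive genes, 9 were higher in male than in female shams, and the list passed with fry (adjusted p = 0.00813) but not by camera with an estimated correlation (adjusted p = 0.0532). With the 18S signal as a covariate the median difference was -0.888 (quartiles -1.13 and -0.622, fry adjusted p = 0.0204). This adjustment leans on male TAC 5, whose 18S signal stood apart (13.2 against 9.11 to 9.57 on the other male TAC arrays). It therefore does not decide whether array quality was the cause. The macrophage list had a median of 0.0508 (quartiles -0.194 and 0.218), which argues against more macrophages in male shams. A sex difference present with either operation stays open: between the TAC groups the median was -0.233 (quartiles -0.343 and -0.068, fry adjusted p = 0.704), but the difference of responses did not pass either (fry adjusted p = 0.412). An exposure or a batch shared by the male shams may also be the cause, which the labels do not allow to be tested.

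Of 11 clock genes, 2 were lower on TAC arrays in males and 4 in females, and the list did not pass with an estimated correlation (adjusted p = 0.211 and 0.19). Over the 8 TAC arrays, less the sex means, the clock score correlated with the fetal gene score at r = -0.451 (permutation p = 0.265, adjusted 0.265 over 2 relations) and rho = -0.19 (permutation p = 0.665, adjusted 0.665), and without the 2 arrays farthest from the median r was 0.895, so a link to load cannot be told. Arntl correlated with the mean of Dbp, Per2, Per3 and Nr1d1 at r = -0.945 (permutation p = 0.00541, adjusted 0.0108) and rho = -0.714 (permutation p = 0.0576, adjusted 0.115), and r was -0.565 without the 2 farthest arrays, so the relation rests on those. They were male TAC 4 and female TAC 1, with an Arntl signal of 32.9 and 22 against 325.9 to 538.4 on the other TAC arrays and a Dbp signal of 3713.5 and 3508.4 against 272.6 to 936.5, while Nr1d1 on female TAC 1, at 384.4, lay within the 290.3 to 660.2 of the other TAC arrays. On the Dbp probe set called in females, signals were 2200 ± 425 in male and 2901 ± 350 in female shams (SD, n = 4). In male and female TAC they were 977 ± 1082 and 843 ± 712. The highest clock scores of male and female TAC, 0.161 and 0.119, lay near the lowest of the shams, 0.196 and 0.194. Standing apart from the other TAC arrays thus need not mean standing apart from the shams. A different time of day of collection may have shifted these genes, but the labels give no time, and time and load cannot be told apart.

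The 18S signal and the Gapdh ratio followed the operation, with r = -0.738 between the 18S signal and TAC and r = 0.827 for the ratio. With the 18S signal as a covariate 1650 of the 3890 averaged calls stayed called in the same direction, and with the Gapdh ratio 579. The threshold allows 95.9 and 32 false calls among the 1917 and 640 calls with the covariate. That limit is a fixed share of the same calls, so exceeding it could hardly fail and decides nothing. The values show only that a linear adjustment for either measure left these calls. Quality that the measures follow in part cannot be removed in this way, and the 18S adjustment leans on male TAC 5. Of the calls that ended, 2240 and 3311, the median share of the log2 fold change kept was 0.846 (quartiles 0.641 and 1.06) and 0.838 (quartiles 0.54 and 1.15), and 99.2% and 95.8% kept their direction. Their median size went from 0.469 to 0.393 and from 0.516 to 0.443 while the median SE went from 0.126 to 0.197 and from 0.125 to 0.253. Both the smaller size and the larger error can end a call, and their shares were not tested call by call. A batch that the labels do not name stays open as a contribution to any TAC difference, and so does load itself.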

How the results depend on the processing

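The covariates, the removal of male TAC 4 together with female TAC 1, and most alternatives for gene lists were chosen after the result was seen. Except where stated, the cause of a change was not tested.

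With 1 probe set per gene, fewer probe sets were tested, and the calls were 1265 in males, 1039 in females, 2138 averaged, 2 for the difference of responses and 2 between the TAC groups. With the 18S signal as a covariate they were 997 in males, 1917 averaged and 26 between the shams, and with the Gapdh ratio 398 in males, 498 in females, 640 averaged and 4 between the TAC groups. The clock gene difference left 1288 calls in females. For the difference of responses a pseudocount of 64 gave 1 call and leaving out the dimmest 60% gave 2. Between the shams there were 21 calls without an intensity trend and 88 with only the groups compared. Between the TAC groups there were 5 without the dimmest 60%, 4 without male TAC 4 and female TAC 1 and 3 with only the groups compared.

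With an estimated correlation the called lists were 10 in males, 8 in females, 8 averaged, 0 for the difference, 1 between the shams and 1 between the TAC groups. Between the TAC groups the lists were 5 with a pseudocount of 64, 6 without a filter, 1 without the dimmest 60%, 5 with the 18S signal and 7 without male TAC 4 and female TAC 1. The correlation of the responses was 0.457 without a filter, 0.758 without the dimmest 60%, 0.733 with the 18S signal and 0.735 with the Gapdh ratio.

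Replicate numbers were tested as a block because they might pair the arrays. Deviations of 13 same-numbered pairs correlated at -0.0302 to 0.115, and 6 were their own best match. The correlations were low, but the matches were not compared with a chance value, so pairing by number stays open. The block gave 2 calls for the difference and 65 between the shams, and 8 lists between the TAC groups.

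Leaving out 1 array at a time gave 1812 to 2493 calls in males, 1615 to 2127 in females, 3519 to 3824 averaged, 0 to 11 for the difference, 17 to 69 between the shams and 6 to 12 between the TAC groups. The called lists ranged from 19 to 22 in males, 17 to 19 in females, 21 to 21 averaged, 4 to 9 for the difference, 7 to 12 between the shams (7 without female sham 4) and 2 to 10 between the TAC groups. The correlation of the responses ranged from 0.631 to 0.668.

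The sign of Ppara in females turned positive with median centring (0.0704), array weights (0.0024), the block (0.0465), the 18S signal (0.21), the Gapdh ratio (0.16), the clock genes (0.0043) and without female TAC 3 (0.04), female TAC 5 (0.19) or female sham 4 (0.04), with a range of -0.27 to 0.19 when 1 array was left out, and averaged with the 18S signal (0.0733). Per2 in males was 0.28 with the Gapdh ratio. With the 18S signal the sarcomere list reversed its direction of test in males (median 0.0363), averaged (-0.0433) and between the shams (-0.0275), and the interferon list did averaged (0.0145). Of the other values of 83 list results, 2436 stayed on their side of the threshold and 187 lost their call, and of 419 gene results 12031 stayed, 725 lost their call and 83 gained one. The deposited scaling and a signal limit of 130.8 bound what dim probe sets can show.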

Other observations

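Some members of lists that were not called changed after TAC. Of 24 antioxidant and detoxification genes, 5 rose and 6 fell in males (5 and 6 adjusted over the list alone), among them Txn1, which encodes thioredoxin (0.73), the glutathione transferase gene Gstm1 (-0.75) and the glutathione peroxidase gene Gpx1 (0.80). In females 4 rose and 2 fell (4 and 3 adjusted over the list alone), with Gstm1 at -0.90, Gpx1 at 0.68 and the metallothionein gene Mt2 at 1.39. Of 19 genes of glucose uptake and glycolysis, 3 rose and 4 fell in males (3 and 4 adjusted over the list alone), with falls of the insulin-responsive glucose transporter gene Slc2a4 (-0.67), Pfkm (-0.52) and Ldhb (-0.39). In females 4 rose and 2 fell (7 and 3 adjusted over the list alone), with Pfkp at 1.12 and Pgam1 at 0.73.

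Of 31 genes of hypertrophic signalling and cardiac transcription factors, 2 rose and 2 fell in males (2 and 2 adjusted over the list alone) and 2 rose and 3 fell in females (2 and 3 adjusted over the list alone). The growth factor gene Igf1 rose by 1.25 in males and 0.90 in females, and the transcription factor gene Mef2a changed by -0.50 and -0.49. Of 8 neurohumoral genes, 2 fell in males (2 adjusted over the list alone): Rgs2, a brake on G-protein signalling, by -1.50, and Corin by -1.09. Of 17 chemokines and cytokines, 5 rose and 1 fell in males (5 and 4 adjusted over the list alone), with Tnfrsf12a at 2.21 and Il1b at 0.81, and 3 rose in females (3 adjusted over the list alone), with Tnfrsf1a at 0.59. The stress gene Herpud1 (-1.04) and the hypoxia factor gene Epas1 (-1.11) fell in males, and the chaperone gene Pdia4 rose in females (1.11). The hormone-sensitive lipase gene Lipe fell in both sexes (-1.08 in males, -0.77 in females), and the glucocorticoid target Klf9 fell in males (-1.01).

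The covariates were added after the data were seen. With the Gapdh ratio as a covariate, the calls named here held for Txn1, Slc2a4, Tnfrsf12a and Lipe in males and for Gstm1, Gpx1, Mt2 and Lipe in females, and the others ended. With the 18S signal as a covariate those of Pfkm, Ldhb, Mef2a, Rgs2, Il1b and Herpud1 ended in males and those of Mef2a and Tnfrsf1a in females. With the clock gene difference as a covariate those of Pgam1 and Tnfrsf1a in females ended. After median centring those of Ldhb in males and Mef2a in females ended, and no call named above in this section ended when 1 array was left out. The genes named are a selection, so this does not hold for all members of these lists. The smooth muscle marker gene Myh11 fell in females (-1.34) and lost its limma call without female TAC 3 (-0.67, adjusted p = 0.0719).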
